A study of Mus musculus with 14 samples.

How the data were processed

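Liver RNA was sequenced from 14 C57BL/6N mice on 3 diets: 4 libraries from mice on a standard chow, 5 from mice on a high-fat Western diet (HFWD) and 5 from mice on the same diet with sugar in the drinking water (HFWD+sugar). Per the labels, ribosomal RNA was removed from total RNA with a Ribo-Zero Gold kit, cDNA was made with NEBNext modules, the libraries passed through 12 cycles of PCR, and paired reads of 100 bp were planned at 50 M per library. The labels do not say whether the libraries kept the strand of the RNA. Groups were taken from the treatment label of each sample. Mice are numbered within a group in the order of the series, so that a number names a mouse and pairs nothing. The labels give each library a number of its own but do not state outright that each came from a separate animal. If they did not, the p-values measure only the spread between these samples.

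The submitters' processing notes name FastQC, TopHat2 2.0 and SAMtools and the mouse build mm9. The read counter, its strand setting, its treatment of reads with several matches and the scaling method are not given in the sources used here. The values are a signal per gene, deposited by the authors as normalized expression values on a linear scale, in 1 table of 22850 gene rows, each with an Ensembl identifier, a symbol, coordinates and a strand. The table held 22369 protein-coding rows and 481 rows of immunoglobulin segments. It held 0 further columns of values per sample. Of its rows, 22438 had the coordinates and strand of the same identifier in the mm9 gene annotation used here (GENCODE, Ensembl identifiers). In every library the lowest value was exactly 1, which 36.7% to 47.1% of the rows took, so a value of 1 is the floor of the table and stands for no or almost no reads. Fold changes of rows near this floor are compressed.

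Depth was estimated from the low values. In each library they lay on steps of one size, the worth of 1 read, from 2.47 to 6.85 units, and on fractions of that step. Of the values up to 20 reads, 55.0% to 65.7% were whole multiples of the step within a tolerance of 0.02, so whole reads could not be recovered, and no count-based test was run. Dividing each library's total by its step gave the equivalent of 3.77 M reads in chow 4, 5.83 M in HFWD 1 and up to 9.34 M in the other libraries, with a median of 8.35 M. These are weighted counts within the listed genes, not the sequencing depth. Replicates were compared by a chi-square statistic over rows. It ran from 7.49 to 66.6 per degree of freedom over 26 pairs within groups, so no library repeated another of its group within sampling noise.

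The analysis used R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8). Values were taken as log2(value + 1), and all log2 differences and folds are on that scale, which understates changes of low rows. Rows above the floor of 1 in at least 4 libraries were kept, which left 14770. The wording fixed beforehand, a value of 1 or more, would have removed no row because of the floor, and the fit without a filter covers that reading. One limma model with 3 group means was fitted to all 14 libraries (lmFit, contrasts.fit, eBayes with a variance trend), with 3 comparisons, 2-sided tests, Benjamini-Hochberg adjustment over all rows of a comparison and a threshold of 0.05 on the adjusted p, with no minimum fold. "Rose", "fell" and "called" refer to this threshold. Errors of group means are SD and errors of log2 differences are SE.

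Before the data were examined, 41 gene lists for pathways and cell types were written from textbook knowledge. The 37 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Each was tested again with the correlation estimated from the data and with fry, which asks whether a list's members move one way on balance without comparing them with other genes. Lists of mitochondrially encoded genes and small nuclear RNAs had no row in the table, and those for B cells and adipocytes had 2 and 1 tested members, so these 4 lists were not tested. Also fixed beforehand was the rule for naming genes: the 8 highest and the 8 lowest called rows by log2 difference, among rows at or above the median level whose groups did not overlap, without predicted genes; the 2 called members with the smallest p of each list; and a panel of metabolic, fibrotic and inflammatory genes whatever their result. Called list members beyond that rule are named without values and were not followed through the alternatives, and not every row the rule picked is described. Where nothing was called, the 5 highest and 5 lowest rows by p were taken. The rows of opposite-strand neighbours named below fall outside that rule where said and were chosen after their values were seen.

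The fit was tested on simulated data with each row's own mean and 0.7 of its spread plus counting noise. In these data 200 rows were changed, all drawn from rows above the median level. Of the rows changed 2-fold, 85% were called in HFWD against chow, 73% in HFWD+sugar against chow and 81% in HFWD+sugar against HFWD. At 4-fold the shares were 99%, 100% and 100%. Among all calls, 7.07%, 3.35% and 4.23% were rows that had not been changed, over 14661, 14644 and 14640 rows tested. In simulated lists for HFWD against chow, the 1 shifted list was called and 0 of the others. There the rows varied independently and all members of the shifted list moved by the same amount. That check therefore cannot tell whether the preset correlation between genes suits the data.

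The alternatives fixed beforehand were other pseudocounts, filters, scalings, variance models and weights, a fit to the groups compared alone, a term for title numbers above 4044 (a possible second set of mice, which the labels do not call a batch), a minimum fold, other list tests, and leaving out each mouse in turn. Leaving out chow 2 and chow 4 together, and tests of opposite-strand neighbour rows in place of the lists' own rows, were added after the data had been seen. Neighbours were searched within 200 kb of each gene. For each group comparison, 100 of the 126 possible splits of its mice into 2 groups of the same sizes were fitted again.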

Results

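Gene expression was measured by RNA sequencing in the livers of 14 C57BL/6N mice. From 7 weeks of age, 4 mice ate a standard chow with about 12% of its energy from fat, 5 ate a high-fat Western diet (HFWD) with 40% of energy from fat, and 5 ate the HFWD and drank water with 42 g/L of sugar at 55% fructose and 45% sucrose (HFWD+sugar). The labels used here give neither the sex of the mice nor the time on the diet. The series asks what the liquid sugar adds to the liver transcriptome of a diet model of non-alcoholic fatty liver disease. The comparisons are therefore each Western diet against chow, and HFWD+sugar against HFWD. Depth, estimated from the steps between low values, was equivalent to 3.77 M counted reads in chow 4, 5.83 M in HFWD 1 and at most 9.34 M elsewhere, so 1 read was worth 2.47 to 6.85 units and values below about 20 units rest on a handful of reads.

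The rows of the table do not always carry the level of the gene they are named for, which bears on each gene below. The row labelled Alb, the gene of albumin, averaged 3036 units over the 14 livers, whereas the row of Rassf6, 126 kb away on the opposite strand, averaged 683498. The row of Ahsg, which encodes the plasma protein fetuin-A, averaged 1273 and that of its opposite-strand neighbour Kng2 averaged 91270. The row of Hpd, an enzyme of tyrosine breakdown, averaged 523 and that of its neighbour Setd1b averaged 90556. A mean of at least 100 in the own row, with a neighbouring row on each strand, was found for 282 genes of the fixed lists. Over these, the highest neighbouring opposite-strand row within 200 kb stood at a median of 2.21 times the gene's own row. The highest same-strand row stood at 0.274 times. Over the hepatocyte list alone the opposite-strand median was 0.703, so the pattern did not hold for each gene. Symbols below therefore name rows of the table, and results for the rows of opposite-strand neighbours are given beside the lists called against chow.

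**Figure D1:**
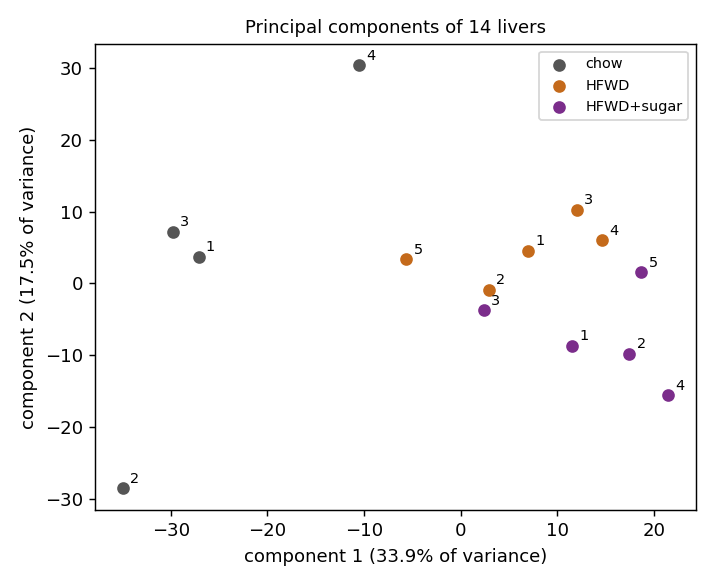
Principal components of log2 values of the 14 livers, component 1 (33.9% of the variance) on the x axis and component 2 (17.5%) on the y axis, with 1 point per mouse, coloured by diet and numbered within its group. The 4 chow mice lie left of the 10 Western diet mice on component 1, and chow 2 and chow 4 lie at opposite ends of component 2.

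The first comparison asked what the HFWD alone changed against chow. Of 14770 rows tested, 361 rose and 138 fell. Rows beside genes of cholesterol synthesis showed several of the deepest falls, the desaturase rows Fads1 and Fads2 fell while Scd1 rose, and the rows of Cidea and Cd36, genes of lipid droplets and fatty acid uptake, rose. The Akap9 row (chromosome 5, 3928054 to 4080209, plus strand) fell from 14552 ± 1921 units (SD, n = 4) on chow to 1525 ± 131 (SD, n = 5) on HFWD, a 9.50-fold fall (adjusted p = 1.59e-10). Akap9 encodes an anchoring protein of the Golgi and centrosome, and its gene ends 0.936 kb from Cyp51, the lanosterol demethylase of cholesterol synthesis, on the other strand. The Wdr37 row (chromosome 13, 8802214 to 8871155, minus strand), 13.6 kb from the isopentenyl diphosphate isomerase gene Idi1 on the other strand, fell from 1105 ± 215 (n = 4) to 79.7 ± 23.1 (n = 5), or 13.9-fold (adjusted p = 2.04e-09). Ash1l, which lies 14.2 kb from the farnesyl diphosphate synthase gene Fdps, and Cetn2, which lies 0.146 kb from the sterol dehydrogenase gene Nsdhl, fell by 2.45 and 2.44 on the log2 scale (SE 0.18 and 0.21).

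The list of cholesterol synthesis genes was lower on HFWD by its own rows too. Of its 23 tested members, 3 fell and none rose (0 of 23), the median log2 difference was -0.43, and adjusted over the list alone 6 fell. The 3 were Pmvk, the phosphomevalonate kinase, which went from 33.3 ± 10.7 (n = 4) to 3.14 ± 2.89 units (n = 5), Fdps, and Sc4mol, the sterol methyl oxidase, which went from 55.4 ± 16.8 to 16.1 ± 2.83. Values this low rest on few reads, and the Sc4mol call ended when both chow 2 and chow 4 were omitted (adjusted p = 0.0894). Camera called the list (adjusted p = 1.07e-05), and fry did as well (adjusted p = 0.00149). With an estimated correlation it was not called (adjusted p = 0.0666). The row of Sqle, the squalene epoxidase of the pathway, did not pass, at 176 ± 17.2 units against 191 ± 24.4 (adjusted p = 0.763). The higher opposite-strand neighbours of 10 members were tested after their values had been seen: 6 of the 10 fell, their median log2 difference was -1.23, and their adjusted p = 2.44e-13 (adjusted p = 0.0139 with an estimated correlation).

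Among the genes of fatty acid synthesis, 1 of 20 rose and 3 fell, with the same counts when adjusted over the list alone, and the list was not called (adjusted p = 0.271). Fads2 and Fads1, the delta-6 and delta-5 desaturases that make polyunsaturated fatty acids, fell 2.66-fold (34064 ± 2363 to 13060 ± 2974 units, adjusted p = 1.05e-05) and 2.23-fold (317 ± 25.3 to 145 ± 34.6, adjusted p = 0.00149). The third was Acly, the ATP citrate lyase. The stearoyl-CoA desaturase Scd1 rose 1.51-fold, from 5161 ± 916 to 7778 ± 1175 units (adjusted p = 0.0145), a call that ended without chow 1 (adjusted p = 0.0546). Fasn and Srebf1, the fatty acid synthase and a lipogenic transcription factor, did not pass (adjusted p = 0.706 and adjusted p = 0.325).

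Of 20 genes of lipid droplets and of PPARG-driven lipid storage, 2 rose (3 when adjusted over the list alone) and none fell (0 of 20), with a median log2 difference of 0.59. Cidea, a lipid droplet fusion protein (chromosome 18, 67503218 to 67527448, plus strand), was at or near the floor on chow, at 1.41 ± 0.827 units (n = 4), and at 27.1 ± 20.7 (n = 5) on HFWD (adjusted p = 0.000289). Cd36, a fatty acid transporter (chromosome 5, 17287508 to 17394777, minus strand), rose 2.69-fold, from 40.2 ± 12.1 to 110 ± 30.1 units (adjusted p = 0.00777). The Gnat3 row on the other strand, 73.7 kb from Cd36, rose from 2740 to 8456 units, while the 15 opposite-strand rows of the list as a set were not called (adjusted p = 0.461). Camera called the list (adjusted p = 0.0356), but not with an estimated correlation (adjusted p = 0.538), nor without chow 1, chow 4 or HFWD 2 (adjusted p = 0.164, adjusted p = 0.304 and adjusted p = 0.0949), nor without both chow 2 and chow 4 (adjusted p = 0.0724), nor by fry (adjusted p = 0.0611). The panel genes Cidec and Plin2, which coat or fuse droplets, and Pparg did not pass (adjusted p = 0.676, adjusted p = 0.975 and adjusted p = 0.395).

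The third list called was that of amino acid breakdown and the urea cycle, in which 1 of 17 fell, also when adjusted over the list alone, with a median log2 difference of -0.23 (adjusted p = 0.00172, and adjusted p = 0.394 with an estimated correlation). That call also ended by fry (adjusted p = 0.0743) and without both chow 2 and chow 4 (adjusted p = 0.0724), and its opposite-strand rows were not called (adjusted p = 0.188). The member was Cps1, the carbamoyl phosphate synthetase that starts the urea cycle, at 7899 ± 2361 units on chow and 3643 ± 979 on HFWD (2.15-fold lower, adjusted p = 0.00713). Among glycolytic genes 2 of 20 rose, among them the bifunctional enzyme Pfkfb1, 1.48-fold (adjusted p = 0.00334), and that list was not called (adjusted p = 0.244), though its opposite-strand rows were called higher (adjusted p = 0.0411, and adjusted p = 0.415 with an estimated correlation). Further members that rose were Abcg5, a sterol exporter of the canalicular membrane (39.7 ± 10.2 to 116 ± 22.1, adjusted p = 0.00289), Vnn1, a pantetheinase controlled by PPARA (18.5 ± 10.9 to 61.3 ± 21.4, adjusted p = 0.0102), and Ephx1, the microsomal epoxide hydrolase (1258 ± 809 to 3307 ± 581, adjusted p = 0.0042). Cyp2b9, a cytochrome P450, was at the floor of 1 in all 4 chow livers and at 29.1 ± 17.7 on HFWD (adjusted p = 0.000337).

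The other rows with the largest differences did not share a list. Srsf3, a splicing factor, rose from 23.6 ± 15.9 to 233 ± 97.7 units (adjusted p = 0.00232), Tmigd1, a membrane protein, from 31.6 ± 23.9 to 359 ± 138 (adjusted p = 5.23e-05), and Impa2, an inositol monophosphatase that lies next to Cidea on chromosome 18, from 49.0 ± 26.5 to 475 ± 331 (adjusted p = 0.000283). Mmp1b, Klhdc4, Prcp, Alpk3 and Gpr98 rose as well, by 2.51 to 2.87 on the log2 scale. Cnga1, a cyclic nucleotide-gated channel, had 767 ± 495 units on chow and 55.1 ± 48.9 on HFWD (adjusted p = 0.000626), and Adcy2, an adenylyl cyclase, had 267 ± 132 and 31.1 ± 14.5 (adjusted p = 0.000377).

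By their own rows, markers of other liver cells were not called as lists. Macrophage genes had 1 riser among 20 (adjusted p = 0.751), genes of fibrosis and stellate cells 0 among 25 (adjusted p = 0.667), interferon-induced genes 1 among 20 (adjusted p = 0.26) and inflammatory cytokines 0 among 15 (adjusted p = 0.244). The interferon-induced gene was Rsad2 (283 ± 32.8 to 530 ± 106, adjusted p = 0.0136), a call that ended without both chow 2 and chow 4 (adjusted p = 0.0574). Lists for lipid-associated macrophages, T and NK cells, neutrophils, sinusoidal endothelium, cholangiocytes, hepatocytes, erythroid cells and pancreatic acinar cells were not called either. In opposite-strand rows the interferon-induced list (adjusted p = 0.00275, and adjusted p = 0.0916 with an estimated correlation) and the erythroid list (adjusted p = 0.0225, and adjusted p = 0.28 with an estimated correlation) were called higher. Of the panel, Cd68, Ccl2, Col1a1 and Fgf21 did not pass, and Timp1, Trem2 and Tnf, with no value above 2.89, were too close to the floor to test.

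**Figure D2:**
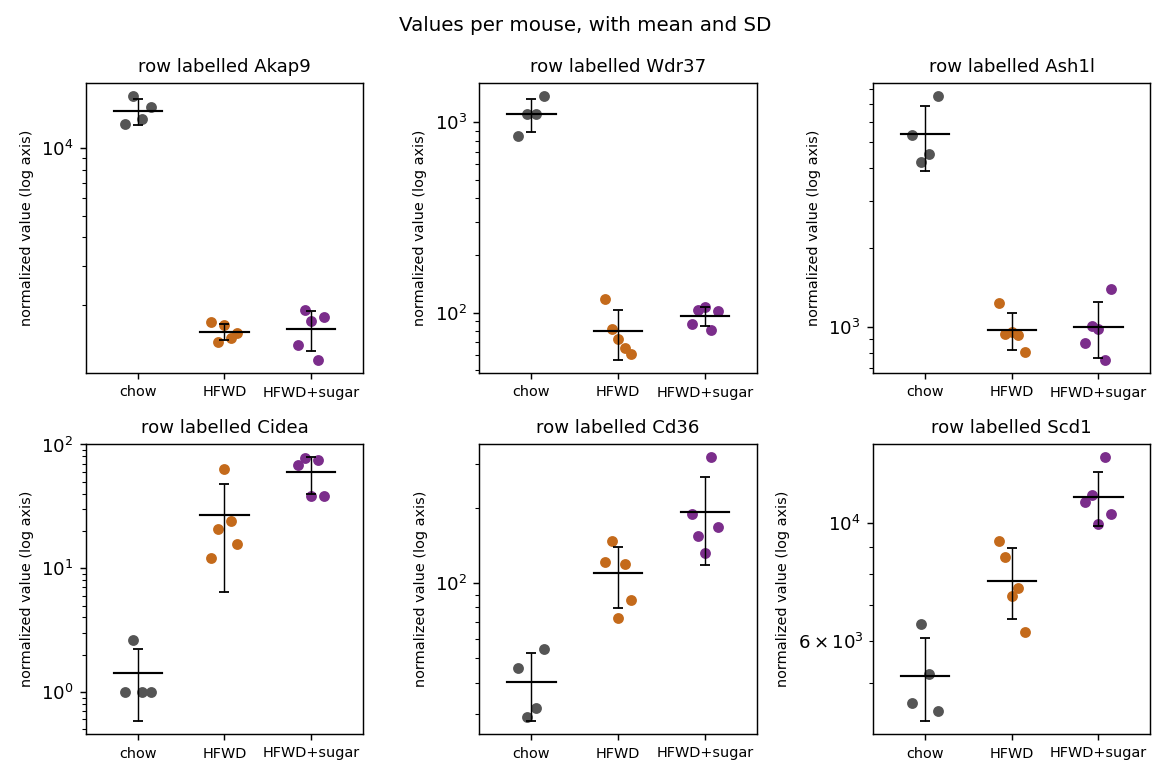
Normalized values of 6 rows in each of the 14 livers on log axes, with 1 point per mouse, the group mean as a horizontal line and the SD as a bar, for chow (n = 4), HFWD (n = 5) and HFWD+sugar (n = 5). In the Akap9, Wdr37 and Ash1l rows all 10 Western diet livers lie below the 4 chow livers, and in Cidea, Cd36 and Scd1 the means rise from chow over HFWD to HFWD+sugar, although no row was called between the Western diets.

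Together 499 rows were called in HFWD against chow by limma, 145 of them at least 2-fold higher and 51 at least 2-fold lower, and 2397 had an unadjusted p under 0.05 where 738 were expected by chance. The count depended on the chow libraries kept. Chow 2 and chow 4 had the lowest array weights (0.444 and 0.349). Without both the count was 916, of which 395 were among the 499, whereas without chow 2 alone it was 505. Leaving out 1 mouse gave 255 (without HFWD 4) to 1051 (without chow 4), with 308, 300 and 326 without chow 1, chow 3 and HFWD 1. Centring each library on its median, which moves the share of higher calls, gave 187 higher and 88 lower.

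The second comparison set HFWD+sugar against chow. Here 837 rows rose and 499 fell, 413 and 110 of them at least 2-fold, and camera called lipid droplet, sugar metabolism, fatty acid oxidation and antioxidant lists higher, and cholesterol synthesis and amino acid lists lower. With an estimated correlation 0 of these 6 lists were called (lowest adjusted p = 0.0987). The median log2 difference over all rows was 0.12, so rises below about that size are no rise against the rest of the table. Over 530 pairs with a far higher opposite-strand row, a gene's own row averaged 1.08% of that row on chow and 1.39% on HFWD+sugar. Exact permutation over 3 comparisons gave adjusted p = 0.0714. Whether this share accounts for rises in own rows against chow was not tested. When each library was centred on its median, 420 rows were higher and 1151 lower, the reverse split, and 919 of the calls were shared. Directions of small differences in this comparison therefore depend on the scaling. The 71 called genes that the naming rule picked kept their sign under each scaling, but they were chosen for being called. Of the 71, 60 stayed called with quantile normalization and 62 with median centring.

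Among lipid droplet and storage genes, 7 of 20 rose (11 when adjusted over the list alone) and none fell (0 of 20, and 1 over the list alone), with a median log2 difference of 1.01. Cidea stood at 59.6 ± 19.6 units (n = 5) against 1.41 ± 0.827 (n = 4) on chow (adjusted p = 5.55e-06), and Cd36 at 193 ± 74.2 against 40.2 ± 12.1, 4.62-fold higher (adjusted p = 0.000113). The others were Mogat1, an enzyme of triglyceride synthesis, Fitm1, a droplet-forming protein, Fabp2, a fatty acid carrier, Lgals1 and Pparg itself. Pparg went from 4.76 ± 3.58 to 16.3 ± 5.39 units (adjusted p = 0.0255), a low level, and its call ended without chow 1, chow 2, HFWD+sugar 1 or HFWD+sugar 4 (adjusted p = 0.0713, adjusted p = 0.0664, adjusted p = 0.0583 and adjusted p = 0.07), and without both chow 2 and chow 4 (adjusted p = 0.0754). Camera gave the list adjusted p = 0.000225, and with an estimated correlation adjusted p = 0.0987. The higher opposite-strand neighbours of its members did not move together (adjusted p = 0.72), although Gnat3 beside Cd36 rose 4.22-fold.

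Genes of fructose and glucose breakdown were higher, with 6 of 20 up (9 when adjusted over the list alone) and 0 down, and a median log2 difference of 0.65. They included Pfkfb1 (450 ± 26.2 to 748 ± 57.4 units, adjusted p = 0.000226), Sord and Gpd1, which handle sorbitol and glycerol phosphate, the fructokinase Khk (330 ± 147 to 622 ± 163, adjusted p = 0.0298) and the pyruvate kinase Pklr (93.6 ± 39.5 to 178 ± 37.1, adjusted p = 0.0399). The Khk call ended without chow 1, chow 4, HFWD+sugar 2, HFWD+sugar 4 or HFWD+sugar 5 (adjusted p = 0.0926, 0.0525, 0.0691, 0.0767 and 0.071). The Pklr call ended without chow 2, chow 3, HFWD 2, HFWD+sugar 1, HFWD+sugar 2, HFWD+sugar 4 or HFWD+sugar 5 (adjusted p = 0.0824, 0.134, 0.0515, 0.0744, 0.0764, 0.0883 and 0.0913), and without both chow 2 and chow 4 (adjusted p = 0.113). Camera called the list (adjusted p = 0.00435), but not with an estimated correlation (adjusted p = 0.378) nor in its opposite-strand neighbours (adjusted p = 0.314). Mlxipl, the carbohydrate-responsive transcription factor, did not pass, at 49.7 ± 11.2 and 60.3 ± 17.2 (adjusted p = 0.578).

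Of 30 genes of fatty acid oxidation and PPARA targets, 8 rose (10 when adjusted over the list alone) and 0 fell. The peroxisomal thiolase Acaa1b rose 2.39-fold (314 ± 43.8 to 756 ± 125, adjusted p = 0.000323) and Vnn1 4.62-fold (18.5 ± 10.9 to 81.6 ± 17.6, adjusted p = 0.00119). Acadm and Cpt1a, an acyl-CoA dehydrogenase and the carnitine palmitoyltransferase of mitochondrial import, were among the other 6. The list's adjusted p = 0.0424, and adjusted p = 0.789 with an estimated correlation. Fry did not call it (adjusted p = 0.109), nor did camera in its opposite-strand rows, where the direction was the other one (adjusted p = 0.776). It was also lost without chow 1, chow 3, chow 4, HFWD+sugar 1 or HFWD+sugar 4 (adjusted p = 0.0699, adjusted p = 0.0861, adjusted p = 0.364, adjusted p = 0.0529 and adjusted p = 0.0839). Antioxidant genes controlled by NRF2 had 6 of 20 up (8 over the list alone) and 0 down, among them Ephx1 (1258 ± 809 to 3620 ± 470, adjusted p = 0.00154) and the glutathione transferases Gstm4 (5.06 ± 4.37 to 18.7 ± 5.15, adjusted p = 0.0254), Gstm1 and Gsta2. Transferases of this family are close in sequence, and how reads shared by them were counted is not stated. The Gstm4 call ended without chow 3, chow 4, HFWD+sugar 1 or HFWD+sugar 4 (adjusted p = 0.074, 0.0552, 0.0564 and 0.067), and without both chow 2 and chow 4 (adjusted p = 0.118). Camera called this list (adjusted p = 0.0233), but not with an estimated correlation (adjusted p = 0.789) nor without chow 3 or HFWD+sugar 4 (adjusted p = 0.0892 and adjusted p = 0.0642), nor in its opposite-strand rows (adjusted p = 0.467).

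Cholesterol synthesis was again lower, with 4 of 23 down (9 when adjusted over the list alone) and 0 up (1 over the list alone), and a median log2 difference of -0.25. They were Pmvk, Fdps, Sc4mol and the sterol reductase Tm7sf2, of which Fdps went from 12.0 ± 6.33 to 1.79 ± 1.77 units (adjusted p = 0.00869) and Sc4mol from 55.4 ± 16.8 to 18.2 ± 8.66 (adjusted p = 0.0105, and adjusted p = 0.0754 without chow 2 and chow 4). The list's adjusted p = 0.000259, and adjusted p = 0.0987 with an estimated correlation. Its opposite-strand neighbours had a median of -1.52, with 6 of 10 down (adjusted p = 8.18e-13, and adjusted p = 0.0163 with an estimated correlation). Akap9 and Wdr37 stood at 1568 ± 317 and 95.8 ± 11.2 units (n = 5 each), near their levels on HFWD. Among genes of amino acid breakdown and the urea cycle 5 of 17 fell (6 over the list alone) and 0 rose. They were Cps1 (7899 ± 2361 to 3016 ± 563, adjusted p = 0.00101), the tyrosine aminotransferase Tat (1376 ± 471 to 481 ± 263, adjusted p = 0.012), Ass1 and Asl of the urea cycle, and Gldc of glycine cleavage. That list had adjusted p = 0.00435, and adjusted p = 0.378 with an estimated correlation. Its opposite-strand rows were lower too (adjusted p = 0.0102, and adjusted p = 0.176 with an estimated correlation). In this comparison, however, 7 of 39 lists were called lower in their opposite-strand rows and 0 higher, so a fall there was not particular to these genes.

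In fatty acid synthesis 2 of 20 rose and 2 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.593). Scd1 rose 2.18-fold, from 5161 ± 916 (n = 4) to 11161 ± 1296 units (n = 5, adjusted p = 3.62e-05), and the fatty acid elongase Elovl5 rose too. Fads2 fell 2.30-fold (adjusted p = 4.72e-05), and Fads1 fell as well. Fasn and Srebf1 had adjusted p = 0.133 and adjusted p = 0.115. Other rises were the betaine-homocysteine methyltransferase Bhmt (385 ± 49.0 to 779 ± 111, adjusted p = 0.000817) and Abcg5 (39.7 ± 10.2 to 119 ± 43.6, adjusted p = 0.00224). Serpina1e, an antitrypsin of the male-biased list, fell 2.74-fold (1248 ± 199 to 467 ± 138, adjusted p = 0.00154), and its paralogs share much of its sequence. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 63.6 ± 54.6 and 193 ± 96.4 units and missed the threshold (adjusted p = 0.0516).

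Camera called no immune or fibrosis list, though single members passed, while fry called interferon-induced genes (adjusted p = 0.0274) and inflammatory cytokines (adjusted p = 0.0422). Macrophage genes had 4 of 20 up and 0 down (adjusted p = 0.14 for the list), among them Cd5l, a protein secreted by macrophages (35.3 ± 12.5 to 106 ± 55.8, adjusted p = 0.0099), and the cathepsin Ctss (14.6 ± 10.2 to 48.1 ± 22.8, adjusted p = 0.0126). Interferon-induced genes had 5 of 20 up and 0 down (adjusted p = 0.0659), with Rsad2 at 283 ± 32.8 and 638 ± 184 (adjusted p = 0.00154). Genes of fibrosis and stellate cells had 2 of 25 up (adjusted p = 0.209): the collagen Col3a1 (15.1 ± 2.52 to 51.7 ± 24.5, adjusted p = 0.0114) and Col5a2, which lies 24.6 kb from it on the other strand and whose call ended without chow 1, chow 3, chow 4, HFWD+sugar 1, HFWD+sugar 2, HFWD+sugar 4 or HFWD+sugar 5 (adjusted p = 0.092, 0.103, 0.0654, 0.0583, 0.0568, 0.101 and 0.0824). Col1a1, Cd68, Ccl2, Plin2 and Fgf21 did not pass, nor did the lists for lipid-associated macrophages, T and NK cells, neutrophils, sinusoidal endothelium, cholangiocytes, hepatocytes, erythroid and pancreatic acinar cells. In opposite-strand rows the hepatocyte list was called lower, with 2 of 5 down and a median log2 difference of -0.33 (adjusted p = 0.00202, and adjusted p = 0.0727 with an estimated correlation). Of 39 lists tested in those rows, 7 were lower, this list among them, and 0 higher.

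Rows outside these lists with the largest rises were Kcnb2, a potassium channel (187 ± 193 to 2097 ± 794 units, adjusted p = 0.00043), Srsf3, Impa2, Tmigd1, Alpk3 (22.9 ± 13.5 to 240 ± 22.7, adjusted p = 1.56e-06), Mmp1b, Hmgn3 and Olfr94. Olfr94 is an olfactory receptor gene 0.613 kb from the ubiquitin-like gene Ubd on the other strand, and its row rose from 28.3 ± 2.11 to 242 ± 83.7 (adjusted p = 1.48e-06). Deep falls besides Akap9 and Wdr37 included those of Cnga1, Adcy2, Hsh2d, Ash1l and Lyrm4, by 2.42 to 3.40 in log2 size. In all, limma called 1336 rows, and 3656 had an unadjusted p under 0.05. Leaving out 1 mouse gave 674 (without HFWD+sugar 4) to 1768 (without chow 4), with 858, 742, 860 and 880 without chow 1, chow 3, HFWD+sugar 2 and HFWD+sugar 5, and 1600 were called without chow 2 and chow 4.

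The effects of the Western diets against chow were compared with each other. Of the rows called, 308 rose in both and 117 fell in both, and 0 were called in opposite directions. Independent lists of these sizes would share 20.5 and 4.66, but the comparisons share their chow livers, which raises the overlap and works against opposite calls, and the overlap without any effect was not simulated. Across the tested rows, which are not independent replicates, the log2 differences had a correlation of 0.753. Both comparisons use the same chow livers, and simulated groups without any effect had a correlation of 0.559 for that reason. With chow split, 2 mice for each effect, the correlation was 0.299 on average over 6 splits (0.219 to 0.340). The covariance was 0.231 against 0.0871 in the simulation, and 0.124 with chow split. The counts of 499 and 1336 do not by themselves show that the diets differ.

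The third comparison tests that difference directly, HFWD+sugar against HFWD, and limma called 0 of 14770 rows. At an unadjusted p under 0.05 there were 1273 rows where 738 were expected, and the lowest adjusted p = 0.46. In the simulation 81% of rows changed 2-fold were called at this size of groups. It used 0.7 of each row's spread and changed only rows above the median level. The share can therefore be lower in the data, and 0 calls do not exclude 2-fold differences. The rows with the lowest p included Elovl5, the fatty acid elongase, at 225 ± 58.1 (n = 5) and 476 ± 132 units (n = 5), Mme, the membrane peptidase neprilysin, at 47.7 ± 7.12 and 97.3 ± 28.7, and the interferon-induced helicase Ddx60 at 3.35 ± 4.21 and 14.2 ± 1.66. They also included C8a, a complement component, at 16904 ± 4670 and 9650 ± 1559, and Arrdc2 at 61.8 ± 8.83 and 34.9 ± 5.39, each with adjusted p = 0.46. Scd1 was at 7778 ± 1175 and 11161 ± 1296 (log2 0.53, SE 0.12, adjusted p = 0.46), Fasn at 70.0 ± 21.5 and 156 ± 55.6 (log2 1.10, SE 0.30, adjusted p = 0.503), and Cd36 at 110 ± 30.1 and 193 ± 74.2 (adjusted p = 0.525). Khk, Pklr, Srebf1, Mlxipl, Cyp7a1, Pparg, Cidea, Cidec, Plin2 and Sqle did not pass, with adjusted p from 0.525 to 0.956.

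Camera called 8 whole lists although 0 of their members were called. With an estimated correlation 0 of the 8 lists were called, with adjusted p = 0.269 for lipid droplets and fatty acid synthesis, adjusted p = 0.612 for endoplasmic reticulum stress, antioxidant and fructose genes, and adjusted p = 0.689 for the rest. By fry too 0 were called, the lowest being fatty acid synthesis (adjusted p = 0.0729). By camera at the preset correlation, lipid droplet genes (median log2 0.58), fatty acid oxidation genes (0.35) and fatty acid synthesis genes (0.20) were higher with sugar, and genes of endoplasmic reticulum stress lower (-0.14), each with adjusted p = 0.000503. Antioxidant NRF2 targets (0.41, adjusted p = 0.00155), xenobiotic genes controlled by CAR and PXR (0.32, adjusted p = 0.0118), lipoprotein export genes (0.26) and fructose and glucose breakdown genes (0.21, adjusted p = 0.0151 for both) were also higher. Adjusted over the list alone, 5 of the 20 fatty acid synthesis genes passed, 1 of 30 in oxidation, 2 up and 1 down of 21 in the xenobiotic list, and 0 in the others. With a term for the possible second set of mice, the calls of fatty acid oxidation and lipoprotein export ended (adjusted p = 0.0955 and adjusted p = 0.0554). The fructose call ended without HFWD 5 or HFWD+sugar 5 (adjusted p = 0.154 and adjusted p = 0.0609). The lipoprotein call ended without HFWD 2, HFWD 3, HFWD 5 or HFWD+sugar 4 (adjusted p = 0.0523 to 0.0802), and the xenobiotic call without HFWD 3, HFWD 5 or HFWD+sugar 4 (adjusted p = 0.0662 to 0.079). In the opposite-strand neighbours of their members 0 of the 7 higher lists were called, and for 6 of the 7 camera gave the other direction there. The list of endoplasmic reticulum stress was lower there too (adjusted p = 0.00344, and adjusted p = 0.095 with an estimated correlation), but so were 6 other lists (hepatocyte, oxidative phosphorylation, ribosomal protein, gluconeogenesis, amino acid, and T and NK cell genes, 0 of them with an estimated correlation), and of 39 lists tested there 7 were lower and 0 higher.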

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

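The screen covered 321 combinations of a named row or library measure with a diet. In 27 of them 1 library was set far apart from the rest of its group. For normally spread values chance alone would give about 1 in 20, or 16.05. Where all other mice of a group were at the floor of 1, however, any higher value was flagged. The 27 therefore cannot be read as an excess over 16.05. Of the tests of explanations in this part, the pair on lists higher with added sugar was set before its result was seen. The tests of the other patterns, the splits of the mice and the spread between mice were chosen only after the result was seen, whereas the estimated correlation and fry were fixed beforehand.

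In chow 2 the highest value of its group was seen in Col5a2 (3.72 units against 1 in the other chow livers), Orm3 (6.63 against 1 to 1.28), Fgf21 (2.65 against 1), Hist1h4i (2.65) and Cidea (2.65 against 1). These values are each about 1 to 3 reads. The same liver had the lowest Junb (655 against 835 to 868) and the lowest Ccl3 (10.3 against 20.2 to 23.1). Chow 4, the library with the fewest reads, had the lowest Ccne2 (2238 against 2641 to 2694) and the lowest Srsf3 (1 against 24.4 to 37.2). The Srsf3 row is among the largest rises on HFWD, and its floor value in chow 4 adds to the size of that rise.

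On HFWD, mouse 5 had the lowest Abcb4 (184 against 374 to 431), the lowest Acaa1b (284 against 487 to 530) and the highest Rsad2 (716 against 453 to 509). Mouse 3 had the highest Fdps (6.08 against 1 to 1.51), the highest Ccl3 (94.8 against 33.2 to 43.8) and the lowest Tef (3996 against 5031 to 5270). Mouse 4 had the highest Gpnmb (2.68 against 1) and the lowest Ccdc11 (21.4 against 49.3 to 58.3), and mouse 2 the lowest Cd68 (6.43 against 13.1 to 15.8) and the highest Col1a1 (3.02 against 1). On HFWD+sugar, mouse 5 had the highest Junb (721 against 552 to 596), Ccl2 (2.604 against 1), Lyrm4 (521.5 against 210 to 236) and Impa2 (799 against 437 to 492.5). Mouse 4 had the highest Fdps (4.95 against 1) and Iigp1 (406 against 253 to 277), mouse 1 the highest Arhgap31 (27.98 against 11.3 to 13.0), and mouse 2 the lowest Capg (1 against 4.90 to 7.81).

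A further 8 gene lists stood out because camera called them between HFWD+sugar and HFWD although 0 single rows were called. With an estimated correlation (adjusted p = 0.269 to 0.689) and by fry (lowest adjusted p = 0.0729) 0 of the 8 were called. Their median log2 differences were 0.20 for fatty acid synthesis, 0.21 for fructose and glucose breakdown, 0.35 for fatty acid oxidation, 0.58 for lipid droplets, 0.26 for lipoprotein export, -0.14 for endoplasmic reticulum stress, 0.41 for antioxidant genes and 0.32 for xenobiotic genes.

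The first pattern weighed is that of liver genes whose values stand in opposite-strand neighbours, as Alb and Rassf6 show. A shift of symbols against values by a fixed number of rows is argued against, since the most common offset covered 27.3% of the hepatocyte list. Counting of reads on the opposite strand could place values this way only if reads outside a gene's bounds were counted for it, since Alb and Rassf6 do not overlap. Whether such counting took place cannot be told from the values. Its test, the opposite-strand over own row, had a median of 0.703 over the hepatocyte list, above the 0.115 of same-strand neighbours and far below what it would need if it held for each gene. The labels do not say whether the libraries kept the strand, so this stays open.

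The second is the lists that were higher with added sugar. If the sugar livers had kept a larger share of reads in a gene's own row, rows outside these lists with a strong opposite-strand row would rise as well. Their median log2 difference was 0.156 (SE 0.0155, 507 rows), against 0.328 (SE 0.0302) for the 148 members and 0.0457 for all rows. These 507 rows were thus higher too, and camera at the preset correlation gave them p = 0.00013 (unadjusted). Their median was just below the bound set for this explanation, but by less than its spread. This explanation therefore cannot be told apart from a change in the genes. A rise of the transcripts with sugar would raise the opposite-strand rows too if those carry these transcripts, and their median was -0.0446 over 94 rows, below 0 by more than its SE over rows (0.0141) and between mice (0.0291). The value met the bound set beforehand, its SE over rows. Rows of a mouse vary together, however, and beside the SE between mice the value is not clearly below 0. These rows thus showed no rise, but they do not decide against one, even on that condition. Camera did not call them with an estimated correlation. In addition, 7 of 39 lists were lower in their opposite-strand rows, so a fall there was not particular to these genes. The condition is the unsettled first pattern, so neither explanation is settled.

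The third is the lower cholesterol synthesis list on HFWD. The chow libraries that stand apart are argued against as its cause: without chow 2 and chow 4 the list kept adjusted p = 0.00558, and its median log2 difference was -0.44 against -0.43. With all libraries the call itself is lost at an estimated correlation (adjusted p = 0.0666). Lower transcripts of the pathway would lower the rows that hold their reads, and the opposite-strand rows had a median of -1.23. That is in line with lower transcripts as a hypothesis only, because it was found and tested on the same data and rests on the unsettled first pattern. Body weight, food intake and the cholesterol content of the diets were not tested.

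Other groupings of the mice were tried for each count of called rows. In HFWD against chow 1 of 100 splits, the real one, gave as many as 499 rows, and the highest other gave 287. In HFWD+sugar against chow it was again 1 of 100, with 842 as the highest other against 1336. In HFWD+sugar against HFWD the real count was 0, so 100 of 100 splits had to give at least as many and the count tests nothing. The highest other split gave 7.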

How the results depend on the processing

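The alternatives that omit both chow 2 and chow 4, and those on opposite-strand rows, were chosen after seeing the data. No paired analysis was possible because no label pairs the mice, and a count-based test was not run for want of whole counts. The cause of a changed result was not tested. For HFWD against chow the 499 calls became 275 with median centring, 240 with only the compared groups, 1021 with array weights, 246 without a variance trend, 196 at 2-fold or more and 916 without chow 2 and chow 4, and leaving out 1 mouse gave 255 (HFWD 4) to 1051 (chow 4). For HFWD+sugar against chow the 1336 became 745 with the compared groups and also 745 without a trend, 2174 with array weights and 523 at 2-fold or more, and 674 (HFWD+sugar 4) to 1768 (chow 4) without 1 mouse. Between the Western diets 0 stayed 0, or 1 without HFWD 1. Camera's 3, 6 and 8 lists became 0, 0 and 0 with an estimated correlation. With fry the 3 became 1, the 6 became 9 and the 8 became 0, and the 3 became 1 without chow 2 and chow 4 and 6 on opposite-strand rows. Without 1 mouse they were 2 to 4, 4 to 9 and 6 to 9. With chow split the correlation of 0.753 was 0.299.

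On opposite-strand rows 7 lists changed direction: fatty acid oxidation in HFWD+sugar against chow (adjusted p = 0.776), and against HFWD fatty acid synthesis (0.465), fructose (0.189), oxidation (0.135), lipoprotein export (0.0520), antioxidant (0.173) and xenobiotic genes (0.559). Panel genes that were not called changed sign, in log2. Plin2, HFWD against chow: -0.021 with median centring, -0.252, -0.0787, -0.0871 and -0.0661 without chow 1, chow 4, HFWD 1 and HFWD 4, up to 0.50 without chow 2. Col1a1 there: 0 without HFWD 2, up to 0.25. Against chow with sugar, Sqle was 0.0161 with array weights, 0.0452 without chow 2, 0.0177 without HFWD+sugar 4 and 0.0630 without chow 2 and chow 4, down to -0.0614 without chow 3. Cd68 was -0.12 with quantile normalization, -0.10 without chow 4 and -0.14 without chow 2 and chow 4, up to 0.55, and Ccl2 was -0.0407 with median centring and 0 without HFWD+sugar 5, up to 0.21. Against HFWD, Mlxipl was -0.12 with quantile normalization, -0.0866 with median centring, -0.0138 without HFWD 1, and -0.0655 and -0.0238 without HFWD+sugar 4 and 5, up to 0.164 without HFWD+sugar 1, and Fgf21 was 0.166 without HFWD 3, down to -0.312 without HFWD+sugar 4. With a term for the possible second set of mice the lists of fatty acid oxidation and lipoprotein export were no longer called against HFWD (0.0955 and 0.0554). Of the 40 and 71 called genes that the naming rule picked, 32 and 57 stayed called with only the compared groups and 32 and 54 without a variance trend. With quantile normalization 38 and 60 stayed called, and with median centring 35 and 62. Leaving out each mouse in turn, 32 and 50 stayed called in every run.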

Other observations

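Rows that neighbour list genes on the other strand held further large differences, and they were chosen after their values were seen. The E430025E21Rik row, 0.806 kb from the squalene epoxidase gene Sqle, fell from 5179 ± 2150 units (SD, n = 4) on chow to 572 ± 37.9 (n = 5) on HFWD (adjusted p = 5.31e-09) and stood at 586 ± 54.3 (n = 5) on HFWD+sugar, whereas the Sqle row itself did not pass. Beside Mogat1, an enzyme of triglyceride synthesis, the BC035947 row rose from 47.6 ± 41.2 to 245 ± 45.98 (adjusted p = 0.000264) and stood at 477 ± 110 with sugar. Art3, beside the interferon-induced chemokine gene Cxcl10, rose from 265 ± 71.4 to 584 ± 112 (adjusted p = 0.00596). Ctcfl, 33.5 kb from Pck1, an enzyme of glucose production, fell from 200362 ± 33642 to 115436 ± 27908 (adjusted p = 0.0306).

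Tested as lists, the opposite-strand rows of ribosomal protein genes were lower in each comparison. On HFWD against chow 1 of 23 fell (adjusted p = 0.00275, and adjusted p = 0.371 with an estimated correlation). Against chow the HFWD+sugar livers had 10 of 23 lower with a median log2 difference of -0.30 (adjusted p = 3.59e-09, and adjusted p = 0.0727 with an estimated correlation), and against HFWD the list had adjusted p = 4.41e-07 (adjusted p = 0.152 with an estimated correlation). By its own rows camera did not call the list in any of these comparisons (adjusted p = 0.244, 0.54 and 0.461). Those own rows went the other way in HFWD+sugar against HFWD, with a median log2 difference of 0.12. Interferon-induced genes were higher in opposite-strand rows on HFWD against chow, with 3 of 16 up and a median of 0.38 (adjusted p = 0.00275, and adjusted p = 0.0916 with an estimated correlation). In HFWD+sugar camera did not call these rows against chow, with 6 of 16 up (adjusted p = 0.0585). Nor were they called against HFWD, where the direction was down (adjusted p = 0.536). The highest same-strand neighbours, tested as a control over 39 lists, gave 0 calls in each of the 3 comparisons.

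The ratio of a gene's own row to its opposite-strand row was measured over 530 pairs in which the opposite-strand row was far higher, whatever the source of the values there. The own row stood at 1.08 ± 0.106% of the opposite-strand row in chow (SD, n = 4), 1.15 ± 0.117% on HFWD (n = 5) and 1.39 ± 0.197% on HFWD+sugar (n = 5). By exact permutation over 3 comparisons the adjusted p was 0.373 for HFWD against chow and 0.0714 for each comparison with HFWD+sugar.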
